A study of Homo sapiens with 7 samples.

How the data were processed

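The series holds 7 RNA-seq libraries of PC-3, a human prostate cancer cell line, after knockdown or overexpression of circCSNK1G3, a circular RNA of the CSNK1G3 locus. Per the labels' protocols, knockdown cells were infected with lentivirus carrying a short hairpin and selected with 3 µg/mL puromycin, and overexpression cells were transfected with 1.2 µg of plasmid and harvested 24 h later. Libraries were made with a stranded poly(A) mRNA kit and sequenced as single-end reads, per the labels' protocols. The deposited table holds whole-number counts per gene, not normalized, as the values show. Per the submitters' processing notes, the tools were STAR 2.5.3a and edgeR 3.12.1 and the genome build was GRCh37; the annotation, the counting program and the strand setting are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene may therefore share counts. Gene counts of poly(A) libraries do not measure the circular RNA itself, so no value is given for it.

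Libraries were grouped by their titles and treatment labels into shGFP control (n = 2), circCSNK1G3 knockdown (n = 2, with hairpins called sh1 and sh2, 1 library each), empty-vector control called vehicle here (n = 2) and circCSNK1G3 overexpression (n = 1). Column names of the table use 38 where the titles use circCSNK1G3, and were matched on the rest of the name. The labels speak of duplicates and do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The table has 60308 Ensembl gene IDs, of which 40729 (67.5%) were matched to a symbol in the supplied name table. IDs without a symbol took 0.26% to 0.34% of each library's counts, and all 7 sample columns were used. Total counts ran from 26269567 to 40666297 per library. A count of 0 allows up to 0.074 to 0.114 CPM (3 counts of the total, counting error only). No replicate pair agreed within sampling noise: the chi-square per degree of freedom was 134 for shGFP, 114 for knockdown and 5.45 for vehicle.

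Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group left 19978 genes, libraries were scaled with TMM factors, and robust quasi-likelihood fits (glmQLFit, glmQLFTest) used all 7 libraries with 4 groups and Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was its size over the square root of the F statistic. The hairpins were also fitted as separate groups. The overexpression group and each hairpin have 1 library, which was assumed to vary like the replicated groups. That assumption matters here, since the biological coefficient of variation was 25.9% for shGFP, 26.9% for knockdown and 5.4% for vehicle, and 21.2% over the 4 groups together. CPM values are TMM-scaled unless stated otherwise.

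Comparisons were knockdown against shGFP, overexpression against vehicle, the difference of these effects, genes past the threshold in both with opposite signs, vehicle against shGFP, each hairpin against shGFP, and sh1 minus sh2. A set of 24 gene lists was fixed before the data were examined: G1/S, G2/M, genes tied to circCSNK1G3 in prostate cancer work, miR-181 targets, casein kinase 1 family, p53 targets, interferon response, NF-kB and inflammation, unfolded protein and integrated stress response, heat shock, cholesterol biosynthesis, hypoxia and glycolysis, immediate early, epithelial-mesenchymal, epithelial junction and keratin, ribosomal protein, nuclear oxidative phosphorylation, mitochondrially encoded, replication-dependent histone, RNA interference machinery, luminal prostate, neural and HEK293-type, fibroblast, and blood cell genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry. The named genes, by a rule fixed before the data were examined, are CSNK1G3, CBX7, CDK1 and CDC25A; the 10 highest and 10 lowest log2 fold changes past the threshold with at least 5 CPM and groups that do not overlap, or the 5 smallest p where too few pass; the 4 members of smallest p of each list past the threshold; and 5 genes per direction for vehicle against shGFP and for sh1 minus sh2. Genes without a symbol were skipped.

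The fits were tested on simulated counts drawn from the real means and library sizes, with each gene's spread pooled over all libraries. The shares recovered and the false calls thus describe arms of equal spread, which these arms do not have. In the knockdown comparison 43% of genes changed by 1 log2 unit and 91% of genes changed by 2 log2 units were recovered, with 12 false among 146 calls. In the overexpression comparison the shares were 12% and 80%, with 12 false among 104 calls. Unchanged groups were simulated against the shGFP libraries in 20 draws, with the spread of each arm; a first version with a spread pooled over all libraries was replaced because it gives the lentiviral libraries too little spread, and both are kept. The differences from another shGFP library for each comparison were taken on log2 of CPM plus 0.5, using the mean of the treated libraries for knockdown and vehicle. Alternatives changed the scaling, the filter, the test (DESeq2 1.42.0, edgeR likelihood ratio, limma-voom), the libraries in the fit and the replicate block. GC content, length and 3' UTR matches came from GENCODE 29 gene models, matched by gene ID, and no coordinates are given because that annotation uses another build. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.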

Results

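Poly(A) RNA was profiled in 7 libraries of PC-3 cells, a line derived from human prostate cancer, in which the circular RNA circCSNK1G3 was knocked down or overexpressed. The knockdown arm held 2 shGFP controls, which carry a hairpin against a gene absent from these cells, and 2 knockdown libraries, with hairpin sh1 in the first and sh2 in the second. The overexpression arm held 2 vehicle controls with empty vector and 1 overexpression library. Total counts were 39911639 and 37950403 for shGFP, 26269567 for sh1, 35041000 for sh2, 40666297 and 26809875 for vehicle and 36481833 for overexpression. Transcripts of the mitochondrial genome took the smallest share in the first shGFP library (9.40%, Wilson 95% interval 9.39% to 9.41%) and the largest in sh1 (19.98%, 19.97% to 20%, counting error only), with 11.94% to 13.51% in the other libraries. The vehicle replicates were closer to each other (r = 0.998 of log2 CPM across genes) than the shGFP replicates (r = 0.985) or the 2 hairpins (r = 0.980). The groups fall in separate arms, and the labels give no sequencing batch.

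CSNK1G3 (ENSG00000151292.17), the casein kinase gene that hosts the circular RNA, was counted at 8460 CPM in the overexpression library and at 49.6 and 45.8 CPM in the vehicle libraries. It was 177-fold higher with overexpression (log2 fold change 7.47 ± 0.33 SE, edgeR adjusted p = 0.000202). In the knockdown libraries it was counted at 22.1 and 31.6 CPM against 30.1 and 43.4 CPM in shGFP, a log2 difference of -0.45 ± 0.24 SE that did not pass the test (edgeR adjusted p = 0.201). These values are of the gene and do not measure the circle: reads from plasmid exons can be counted as the gene, and a hairpin against the circle need not lower the linear transcript.

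The knockdown comparison asked which transcripts differ when circCSNK1G3 is lowered. Genes of cell division fell together in both knockdown libraries. CDK1 (ENSG00000170312.15), the kinase that drives entry into mitosis, fell from 105 ± 19.4 to 13.1 ± 5.79 CPM (SD, n = 2 each), and CDC25A (ENSG00000164045.11), the phosphatase that activates cyclin-dependent kinases, fell from 31.6 ± 0.968 to 3.94 ± 0.117 CPM (SD, n = 2 each). Of 54 G2/M phase genes 50 fell and 0 rose, with a median log2 fold change of -2.23. Among them were GTSE1 (-3.14 ± 0.20 SE), KIF23 (-2.81 ± 0.19 SE), NEK2 (-2.77 ± 0.18 SE) and HMGB2 (-2.70 ± 0.16 SE). Of 45 G1/S phase genes 35 fell and 1 rose, with a median of -1.24, and CDC45 (-3.80 ± 0.27 SE), RAD51AP1 (-2.78 ± 0.25 SE), CDC6 (-2.64 ± 0.19 SE) and BLM (-2.28 ± 0.21 SE), which serve DNA replication and repair, fell. Adjusted over the list alone, 50 G2/M genes and 38 G1/S genes fell. By limma's camera test both lists were lower than other genes (adjusted p = 1.76e-60 for G2/M and 1.95e-20 for G1/S). Neither call held with a correlation estimated from the data (camera adjusted p = 0.253 with an estimated correlation for G2/M and adjusted p = 0.535 with an estimated correlation for G1/S). By fry both lists were called lower (adjusted p = 0.00864 for G2/M and 0.0328 for G1/S).

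CDK1, CDC25A and CBX7 are genes that earlier work on prostate cancer tied to this circular RNA, so they are not independent evidence if that work used these samples. CDK1 was 8.07-fold lower in the knockdown (log2 fold change -3.01 ± 0.30 SE, edgeR adjusted p = 0.000738) and CDC25A 8.02-fold lower (-3.00 ± 0.18 SE, edgeR adjusted p = 0.000213). CBX7 (ENSG00000100307.12), a Polycomb protein, rose 2.59-fold (1.37 ± 0.34 SE, edgeR adjusted p = 0.0212), from 11.6 and 6.04 CPM in shGFP to 27.2 and 18.6 CPM. The CBX7 call was lost without the first knockdown library (edgeR adjusted p = 0.11) and without the second shGFP library (edgeR adjusted p = 0.0719), and against a fold of 1.5 (edgeR adjusted p = 0.079). As a list the 3 genes had 2 lower and 1 higher, the same adjusted over the list alone, and camera called the list lower (adjusted p = 0.000755, adjusted p = 0.342 with an estimated correlation).

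**Figure D1:**
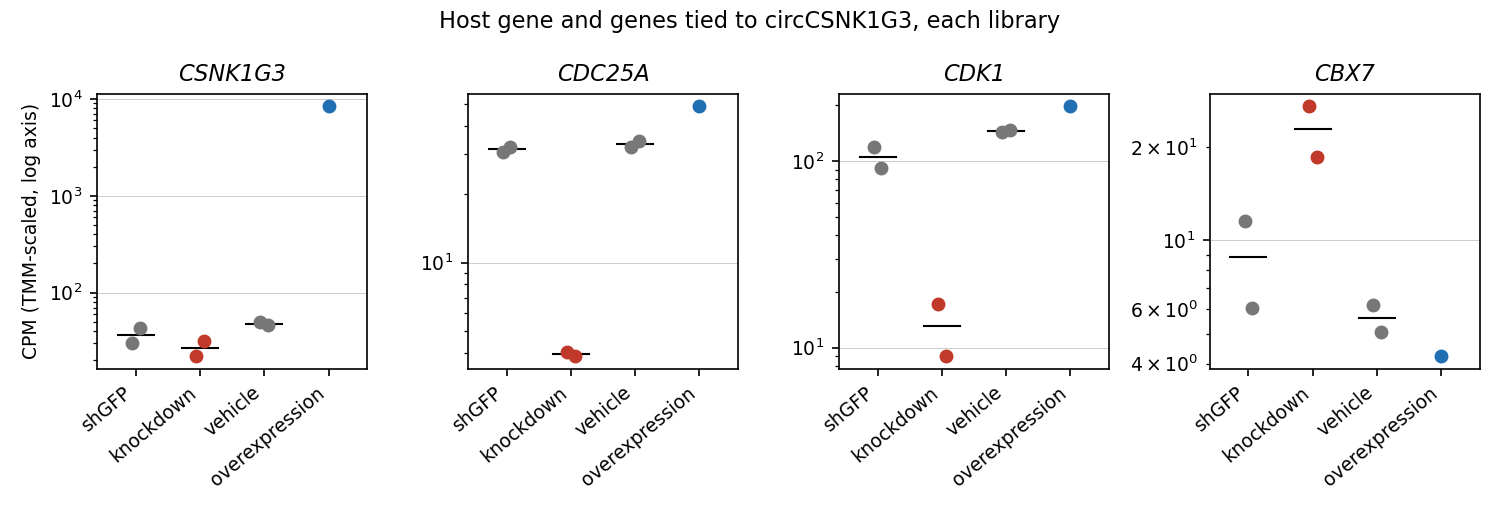
TMM-scaled CPM of CSNK1G3, CDC25A, CDK1 and CBX7 on log axes, with a point per library and a line at the mean of groups of 2. The knockdown libraries lie at 3.86 to 4.02 CPM for CDC25A and the overexpression library at 8460 CPM for CSNK1G3.

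Interferon response genes, which encode antiviral and antigen-processing proteins, rose in the knockdown libraries. Of 53 measured genes 38 rose and 0 fell (46 rose adjusted over the list alone), with a median log2 fold change of 2.32. IFITM1 (4.74 ± 0.51 SE), IFI44L (3.71 ± 0.44 SE), IFITM3 (2.22 ± 0.25 SE) and PSMB8 (2.13 ± 0.26 SE) were the members of smallest p. The list was higher than other genes by limma's camera test (adjusted p = 2.43e-18), and the call was lost with a correlation estimated from the data (camera adjusted p = 0.634 with an estimated correlation). It was not called by fry (adjusted p = 0.143). Several of the highest fold changes rest on the sh2 library: RSAD2 was at 9.57 CPM in sh1 and 279 CPM in sh2, against 2.14 and 4.43 CPM in shGFP. CXCL10 (5.63 ± 1.08 SE), XAF1 (5.55 ± 1.18 SE), RSAD2 (5.46 ± 1.34 SE), MX2 (4.84 ± 1.06 SE) and CMPK2 (4.58 ± 1.13 SE) no longer passed with the knockdown arm fitted alone, with edgeR adjusted p = 0.0508, 0.0964, 0.121, 0.0972 and 0.122. They also missed the threshold without the first vehicle library (edgeR adjusted p = 0.0791, 0.163, 0.195, 0.164 and 0.196), the second vehicle library (0.0836, 0.171, 0.204, 0.172 and 0.205, adjusted) or the first shGFP library (0.0581, 0.0508, 0.118, 0.0873 and 0.117, adjusted). Without the second shGFP library RSAD2, MX2 and CMPK2 missed it (edgeR adjusted p = 0.0942, 0.0606 and 0.0785), and CMPK2 without the second knockdown library (log2 fold change 1.51, edgeR adjusted p = 0.0565). MX1 (4.57 ± 0.79 SE) missed it without either vehicle library (edgeR adjusted p = 0.0632 and 0.0671). In the edgeR fit without a filter on low counts CXCL10, XAF1, RSAD2, MX2, CMPK2 and MX1 missed it (adjusted p = 0.172, 0.21, 0.269, 0.222, 0.27 and 0.139), and by limma-voom RSAD2 and CMPK2 (adjusted p = 0.114 and 0.076). The list had 26 members higher with the knockdown arm fitted alone.

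Other lists were lower in the knockdown. Cholesterol synthesis genes had 16 of 27 members lower and 2 higher (median -0.83; 17 lower adjusted over the list alone), with IDI1 (-2.92 ± 0.19 SE) and INSIG1 (-2.42 ± 0.20 SE) among those that fell. Inflammatory genes had 14 of 30 lower and 2 higher (median -0.85; 15 lower adjusted over the list alone), including the cytokines CSF2 (-4.01 ± 0.40 SE), IL1B (-2.54 ± 0.34 SE) and CSF3 (-2.39 ± 0.44 SE). Immediate early genes had 10 of 32 lower and 1 higher (median -0.71; 14 lower adjusted over the list alone), with the matrix protein gene CCN1 at -3.97 ± 0.21 SE and MYC at -0.97 ± 0.17 SE. Nuclear oxidative phosphorylation genes had 16 of 42 lower and 0 higher (median -0.46; 20 lower adjusted over the list alone), such as COX6C (-1.10 ± 0.15 SE), and 7 lower with the knockdown arm fitted alone. Heat shock genes had 7 of 17 lower and 1 higher (median -0.47; 9 lower adjusted over the list alone), with HSPD1 at -1.21 ± 0.19 SE. Against a fold of 1.5 MYC missed the threshold (edgeR adjusted p = 0.0606). By limma's camera test the adjusted p were 7.21e-08 for cholesterol, 0.000351 for inflammation, 0.000891 for immediate early, 0.000131 for oxidative phosphorylation and 0.026 for heat shock genes. With an estimated correlation the camera values were adjusted p = 0.342, 0.253, 0.634, 0.634 and 0.681 in that order. By fry the adjusted p were 0.0218, 0.00864, 0.0982, 0.0593 and 0.083 in the same order. The heat shock call was also lost without the first shGFP library (camera adjusted p = 0.266) or the first knockdown library (camera adjusted p = 0.11).

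The 13 protein-coding genes of the mitochondrial genome had positive fold changes (median 0.66), of which MT-ND6 alone rose (1.91 ± 0.43 SE, edgeR adjusted p = 0.0148; 1 adjusted over the list alone). MT-ND6 lost its call without the first knockdown library (edgeR adjusted p = 0.0828) or the second shGFP library (edgeR adjusted p = 0.0733). Camera called the list higher (adjusted p = 0.0484, adjusted p = 0.72 with an estimated correlation). The call was lost without the first knockdown library (camera adjusted p = 0.523) or the first shGFP library (camera adjusted p = 0.599).

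The remaining 14 lists were not called in the knockdown. The miR-181 target list had 5 higher and 7 lower of 43 (median -0.28; 8 lower adjusted over the list alone; camera adjusted p = 0.137), with BRCA1 (-2.48 ± 0.29 SE), KLF6 (-2.33 ± 0.43 SE), HMGB1 (-1.10 ± 0.15 SE) and PDCD4 (-0.94 ± 0.16 SE) among those that fell. Against a fold of 1.5 PDCD4 missed the threshold (edgeR adjusted p = 0.0665). CBX7, also on the miR-181 target list, was among those that rose (1.37), a call that did not hold in every alternative. That list was called lower without the second shGFP library (camera adjusted p = 0.0372) or the second knockdown library (camera adjusted p = 0.011). Counts of members higher and lower were 0 and 0 of 6 for the casein kinase family, 4 and 6 of 26 for p53 targets, 7 and 1 of 31 for the unfolded protein and stress response, 5 and 1 of 32 for hypoxia and glycolysis, 6 and 9 of 29 for epithelial-mesenchymal genes and 8 and 5 of 25 for epithelial junction genes. They were 2 and 2 of 50 for ribosomal proteins, 0 and 0 of 20 for histones, 1 and 4 of 14 for RNA interference machinery, 3 and 5 of 18 for luminal prostate genes, 3 and 1 of 10 for neural genes, 3 and 2 of 10 for fibroblast markers and 0 and 0 of 4 for blood markers. Adjusted over the list alone, the counts that differed were 4 and 1 for hypoxia, 6 and 10 for epithelial-mesenchymal, 10 and 5 for epithelial junction, 0 and 0 for ribosomal, 3 and 7 for luminal, 4 and 1 for neural and 4 and 2 for fibroblast genes. Medians of these lists ran from -0.47 (histones, -0.36 with members at 0 counts at their bound) to 0.65 (fibroblast markers). The unfolded protein list was called higher without the first knockdown library (camera adjusted p = 2.32e-07) or the second shGFP library (camera adjusted p = 0.0372). Without the second shGFP library hypoxia genes were called higher (camera adjusted p = 0.00484) and ribosomal protein genes lower (camera adjusted p = 0.0286). Epithelial junction genes were called higher without the first shGFP library (camera adjusted p = 0.0297) or the first knockdown library (camera adjusted p = 0.0151), and epithelial-mesenchymal genes lower without the second knockdown library (camera adjusted p = 0.014).

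The largest decreases past the threshold were of CST4 (-5.34 ± 0.68 SE) and CST1 (-4.22 ± 0.77 SE), which encode secreted cystatins, DEPDC1 (-4.67 ± 0.26 SE), LDB3 (-4.65 ± 0.26 SE), LAPTM5 (-4.41 ± 0.33 SE), TGFBI (-4.41 ± 0.31 SE), PLAC8 (-4.33 ± 0.43 SE), PAEP (-4.16 ± 0.21 SE) and AADACP1 (-4.03 ± 0.39 SE). TGFBI, an extracellular matrix protein gene, went from 421 ± 23.8 to 19.9 ± 8.62 CPM (SD, n = 2 each). Vehicle means also lay far below shGFP for CST4 (0.247 CPM), CST1 (0.721 CPM), LDB3 (1.23 CPM), PAEP (1.42 CPM), LAPTM5 (3.53 CPM) and PLAC8 (5.01 CPM). For these genes a high level particular to shGFP cannot be told from a fall in the knockdown. Vehicle means of DEPDC1 (47.7 CPM), TGFBI (225 CPM) and AADACP1 (16.3 CPM) lay well above the knockdown means. Among the largest increases outside the interferon list were those of CD74, the invariant chain of antigen presentation (5.10 ± 0.60 SE), and GBP1P1 (5.07 ± 0.87 SE). CST1 lost its call without the first knockdown library (edgeR adjusted p = 0.0518), without either vehicle library (edgeR adjusted p = 0.065 and 0.0674) or without a filter on low counts (edgeR adjusted p = 0.151). In all, 2418 genes rose and 2772 fell by edgeR's quasi-likelihood test, of 19978 tested, and 3298 of these 5190 changed by at least 1 log2 unit. The spread behind these calls was pooled over all groups, including the tight vehicle pair, which is not part of this comparison. Fitting the knockdown arm alone gave 3178 genes (1478 higher, 1700 lower); it was 3167 without the first vehicle library, 3175 without the second and 2063 against a fold of 1.5. Upper-quartile scaling moved the median of all genes by 0.134 and turned the split to 3063 higher and 2148 lower.

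Each hairpin was compared with shGFP to ask whether the changes were seen with both. G2/M genes fell with both: 49 of 54 with sh1 (median -1.98) and 49 with sh2 (median -2.65). Interferon genes rose more with sh2, where 49 of 53 rose (median 3.03), than with sh1, where 33 rose and 2 fell (median 1.33). The fitted medians include members at 0 counts, and with these at their bound the sh1 median was 1.37. The difference of the hairpins was tested directly, but each is 1 library, so its SE and p rest on the spread of the shGFP and vehicle pairs and do not separate a hairpin from a library. In sh1 minus sh2 the interferon list had a median of -1.91 and was called by camera (adjusted p = 9.73e-93, adjusted p = 0.381 with an estimated correlation), with 10 members lower and 49 lower adjusted over the list alone. RSAD2 (-4.87 ± 0.46 SE), OASL (-3.34 ± 0.31 SE), DDX60L (-2.86 ± 0.18 SE), IFIT2 (-2.79 ± 0.18 SE) and TRANK1 (-2.66 ± 0.19 SE) were lower in the sh1 than in the sh2 library. LINC00261 (2.38 ± 0.18 SE), RFLNB (2.61 ± 0.25 SE) and TUBB4A (2.02 ± 0.19 SE) were higher in sh1. In total 35 genes differed between these libraries (4 higher and 31 lower in sh1) by edgeR's quasi-likelihood test. DESeq2 gave 461, the edgeR likelihood ratio test 777, a fit without a filter on low counts 1093 and a filter at a mean of 5 CPM 7, without RSAD2, OASL, RFLNB and TUBB4A. By limma-voom RFLNB missed the threshold (adjusted p = 0.055). Without the first or second shGFP library the count was 5830 or 5817.

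Over all genes 5121 changed with sh1 and 3740 with sh2, of which 1170 rose with both and 1608 fell with both, where independent lists would share 201.8 and 280.7. Both comparisons use the same shGFP libraries. Simulated unchanged groups gave 0 shared genes in either direction in 20 draws, with a mean of 0 genes lower in either comparison, so this count does not size the effect of sharing controls. The fold changes of the hairpins had r = 0.71 and a covariance of 1.255 across genes, against r = 0.28 and a covariance of 0.137 in the simulated groups, a covariance difference of 1.118. Each hairpin against a different shGFP library gave r = 0.69 and 0.67. Over genes of 5 CPM or more, with the shGFP libraries shared, the hairpins had r = 0.84 and a covariance of 0.679. The simulated groups were not summarized for that set of genes. No split leaves 2 shGFP libraries per hairpin, so part of the excess in called genes may come from the shared controls. Without either shGFP library the counts were 11475 and 11134 for sh1 and 10567 and 10282 for sh2, and without either vehicle library 2962 and 2978 for sh1 and 2040 and 2056 for sh2.

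**Figure D2:**
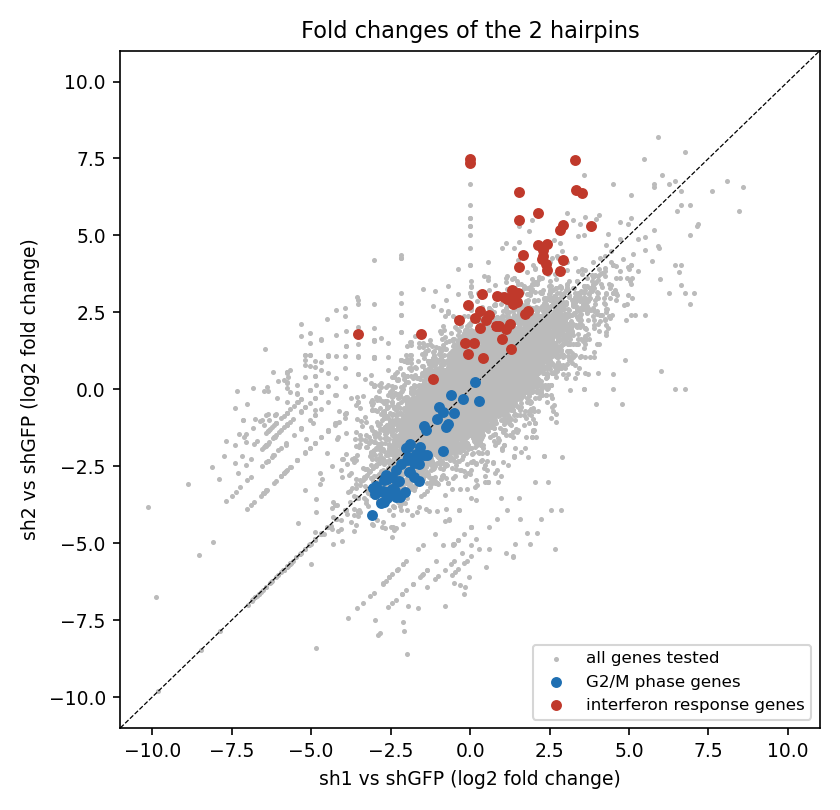
Log2 fold change of sh1 against shGFP (x axis) and of sh2 against shGFP (y axis) for 19978 genes, with G2/M phase genes in blue, interferon genes in red and the dashed line at equal values. G2/M genes (medians -1.98 and -2.65) lie at the lower left, and most interferon genes lie above the line (medians 1.33 and 3.03); stripes of grey points are genes with few or no counts in a library.

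Overexpression was compared with vehicle to ask which transcripts differ when the circular RNA is raised. CSNK1G3 was the only gene past the threshold by edgeR's quasi-likelihood test, with 427 genes at an unadjusted p under 0.05. DESeq2 called 7 genes, the edgeR likelihood ratio test 6 and the fit without a filter on low counts 20. The genes of next smallest p did not pass that test: ARC, an immediate early gene, had a log2 difference of 1.96 ± 0.26 SE (edgeR adjusted p = 0.402), and IDO1, an interferon-inducible tryptophan enzyme, had -2.20 ± 0.28 SE (edgeR adjusted p = 0.402). Both passed by DESeq2 (adjusted p = 3.83e-06 and 9.16e-08), by the edgeR likelihood ratio test (adjusted p = 3.73e-06 and 1.77e-06) and in the edgeR fit without a filter (adjusted p = 2.03e-06 and 2.37e-07). HSPA1A (0.93 ± 0.17 SE, shared reads with HSPA1B possible), ANGPTL4 (1.11 ± 0.27 SE), PLIN2 (0.72 ± 0.18 SE), MMP13 (-1.77 ± 0.29 SE), AGR2 (-1.32 ± 0.23 SE) and SLITRK6 (-1.18 ± 0.27 SE) did not pass edgeR's quasi-likelihood test either. MMP13 and AGR2 passed by DESeq2 (adjusted p = 0.000111 and 0.00165), by the edgeR likelihood ratio test (adjusted p = 0.000603 and 0.0249) and without a filter, HSPA1A by DESeq2 (adjusted p = 0.0119), and ANGPTL4 and SLITRK6 in the edgeR fit without a filter (adjusted p = 0.0482 and 0.0281). CDC25A differed by 0.55 ± 0.19 SE, CDK1 by 0.45 ± 0.33 SE and CBX7 by -0.42 ± 0.43 SE, none of which passed edgeR's quasi-likelihood test. There is 1 overexpression library, so the difference has no replicate check of its own.

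The fit borrows its spread from pairs that are looser than the vehicle pair. Fitted on the 3 libraries of the overexpression arm, where 1 residual degree of freedom comes from the vehicle pair, 946 genes were higher and 1278 lower by edgeR's quasi-likelihood test. That count takes the overexpression library to be as close to its group as the vehicle replicates are to each other, which the data do not show. In that fit CDC25A (0.55, edgeR adjusted p = 1.93e-05) and CDK1 (0.44, edgeR adjusted p = 2.42e-05) were higher, and CBX7 did not pass (-0.44, edgeR adjusted p = 0.0964).

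As lists, interferon genes were lower in the overexpression library: 53 of 53 had negative fold changes (median -1.07). By edgeR's quasi-likelihood test 0 members passed, over all genes or adjusted over the list alone, with 7 at an unadjusted p under 0.05. DESeq2, the edgeR likelihood ratio test and limma-voom also gave 0. In the edgeR fit without a filter BST2 and GBP1 passed (adjusted p = 0.0177 and 0.0235), and the overexpression arm fitted alone gave 52 members. STAT2 was at 106 CPM against 201 and 192 CPM in vehicle, and BST2 at 12 against 31.2 and 30.2 CPM. Unfolded protein and stress response genes had a median of -0.39, with HSPA5, the endoplasmic reticulum chaperone BiP, at 2590 against 4860 and 5090 CPM. Histone genes had a median of -0.59, and their near-identical copies make single genes uncertain. By edgeR's quasi-likelihood test 0 members of the unfolded protein and histone lists passed, and 4 and 3 were lower at an unadjusted p under 0.05. The histone gene H2BC21 passed in the edgeR fit without a filter (-1.26, adjusted p = 0.0294). Fitted on the overexpression arm alone 19 and 10 were lower. G1/S genes had positive fold changes in 45 of 45 (median 0.30), G2/M genes in 45 of 54 (median 0.12), heat shock genes in 14 of 17 (median 0.34; 1 higher adjusted over the list alone and by DESeq2), oxidative phosphorylation genes in 39 of 42 (median 0.13) and ribosomal protein genes in 39 of 50 (median 0.11). Fitted on the overexpression arm alone 25 G1/S, 11 G2/M, 11 heat shock, 4 oxidative phosphorylation and 4 ribosomal protein genes were higher and 0 lower. The casein kinase family was called through CSNK1G3 alone, with a median of -0.04 and a mean of 1.19. By fry only the casein kinase and histone lists were called. Fry did not call the interferon, unfolded protein, heat shock, G1/S, G2/M, oxidative phosphorylation or ribosomal protein lists. By limma's camera test the adjusted p were 2.07e-27 for interferon, 1.58e-08 for unfolded protein, 2.06e-06 for histone, 9.52e-10 for G1/S, 0.00158 for G2/M, 6.63e-08 for heat shock, 0.00133 for oxidative phosphorylation, 0.0163 for ribosomal protein and 4.40e-12 for casein kinase genes. No list was called with an estimated correlation (camera adjusted p = 0.633 for interferon, unfolded protein, heat shock and G1/S, 0.144 for histone, 0.74 for G2/M, 0.717 for oxidative phosphorylation, 0.793 for ribosomal and 0.12 for casein kinase genes, each adjusted p with an estimated correlation). The ribosomal call was lost without the second vehicle library (camera adjusted p = 0.138). Of the 15 lists that were not called, hypoxia genes (median 0.13) were called higher without the first or second shGFP library (camera adjusted p = 0.0379 and 0.0435). With the overexpression arm fitted alone 13 lists were called, among them hypoxia genes (camera adjusted p = 0.0117) and the 3 genes tied to this circular RNA (adjusted p = 0.047) higher, and p53 targets (adjusted p = 0.0154) and immediate early genes (adjusted p = 0.002) lower. Epithelial-mesenchymal genes had a median of -0.02 and a mean of -0.13 where camera's direction was higher (adjusted p = 0.839).

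**Figure D3:**
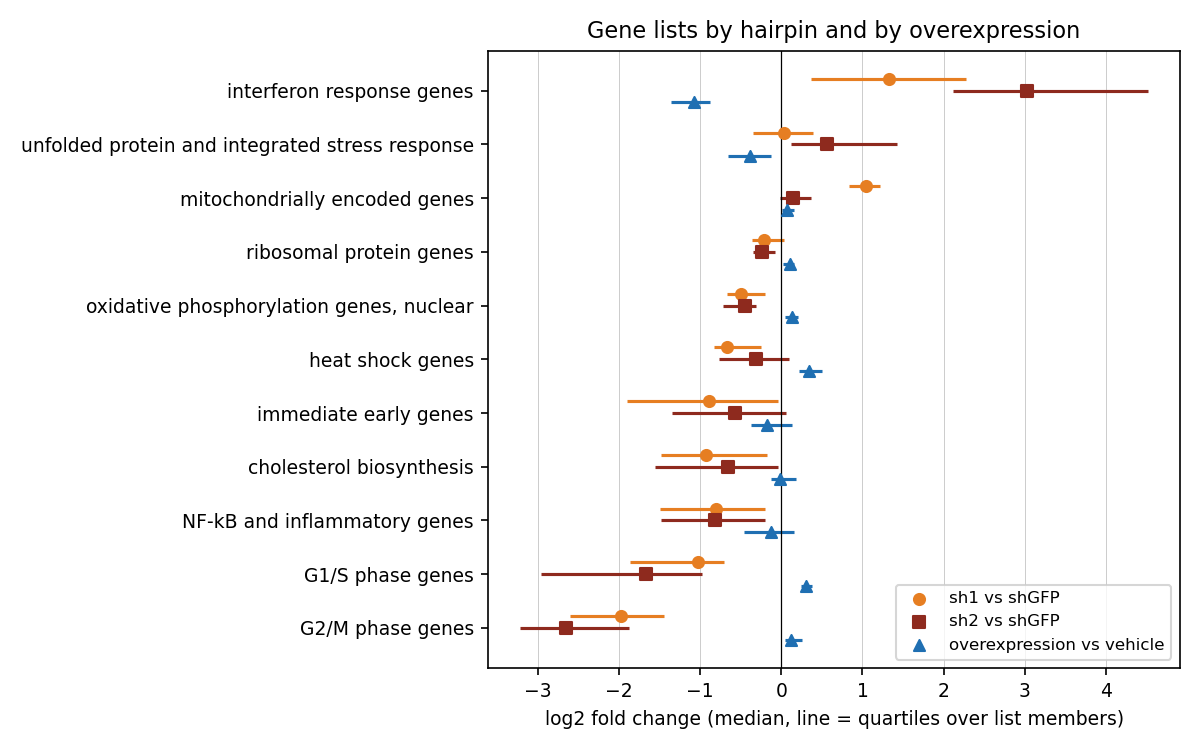
Median log2 fold change of 11 gene lists for sh1 and sh2 against shGFP and for overexpression against vehicle, with lines from the lower to the upper quartile of list members. Interferon genes have medians of 1.33 (sh1), 3.03 (sh2) and -1.07 (overexpression), and G2/M genes of -1.98, -2.65 and 0.12.

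The design sets a knockdown beside an overexpression, and the arms were compared to ask which genes moved oppositely in them; the circular RNA itself was not measured. By edgeR's quasi-likelihood test 0 genes passed in both comparisons, since CSNK1G3 alone passed in the overexpression. At an unadjusted p under 0.05, 145 genes had opposite and 44 the same signs; limma-voom gave 0 genes, DESeq2 gave 3 such genes, the edgeR likelihood ratio test 2 and the fit without a filter on low counts 9. Across the 19978 genes the fold changes of the arms had r = -0.172 and rho = -0.186, and genes are not independent replicates. With each arm fitted alone, a choice made after seeing the data, 449 genes passed in opposite directions: 189 higher in the knockdown and lower in the overexpression, where independent lists would share 96.6, and 260 the other way, where they would share 91.9. In the same direction 47 were higher in both (73.5 by chance) and 57 lower in both (120.8 by chance). These overlaps take the single overexpression library to be as close to its group as the vehicle replicates are to each other. The data do not show that, so the excess is not evidence of opposite regulation. The test of the difference between the effects called 955 genes with a more positive effect of overexpression and 533 with a more negative one. G2/M genes took part in the first (46 of 54, median 2.48) and interferon genes in the second (26 of 53, median -3.41). Such a call can come from the knockdown alone. The G2/M medians were -2.23 in the knockdown and 0.12 in the overexpression, and the interferon medians 2.32 and -1.07. In the overexpression 0 members of either list passed edgeR's quasi-likelihood test, so these calls of the difference test do not show opposite movement. Leaving out the first or second vehicle library lowered the count from 1488 to 219 or 268. It was 2503 without the second knockdown library, and upper-quartile scaling, which moved the median by -0.155, gave 674 higher and 695 lower. DESeq2 gave 2773, the edgeR likelihood ratio test 3022, the fit without a filter 3233 and the hairpins as separate groups 2671. By limma's camera test the adjusted p were 9.26e-62 for G2/M and 1.03e-28 for interferon genes, and adjusted p = 0.328 with an estimated correlation and 0.458 in that order.

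Vehicle and shGFP cells differ in delivery, by transfection or by lentivirus with selection, and were compared to size the difference between the arms. Interferon genes were higher in vehicle, with 45 of 53 higher (median 2.79), including RSAD2 (5.61 ± 1.35 SE), MX2 (5.27 ± 1.08 SE) and CXCL10 (5.11 ± 1.06 SE). Vehicle was also higher in G1/S (31 of 45, median 1.17) and G2/M genes (40 of 54, median 0.98), and in unfolded protein genes (12 of 31, median 0.99). KLHDC7B (5.63 ± 0.73 SE) and HIF1A-AS3 (4.93 ± 0.31 SE), an antisense gene whose reads cannot be told from those of HIF1A without a stated strand setting, were higher. PAEP (-7.26 ± 0.25 SE), CST4 (-6.90 ± 0.76 SE), CST1 (-6.47 ± 0.89 SE) and LDB3 (-5.12 ± 0.26 SE) were lower, and LILRB1 was at 10.3 and 23.5 CPM in shGFP and at 0.0737 and 0 CPM in vehicle. Cholesterol genes were lower (16 of 27, median -0.73), and histone genes higher (12 of 20, median 1.72). Adjusted over the list alone, 47 interferon, 38 G1/S, 45 G2/M, 15 unfolded protein and 16 histone genes were higher and 19 cholesterol genes lower. Camera also called inflammatory genes higher (median 0.71, adjusted p = 6.13e-06) and epithelial junction (-0.35, 0.00183), ribosomal protein (-0.31, 0.00741), oxidative phosphorylation (-0.32, 0.00172) and luminal prostate genes (-0.38, 0.0191) lower, none of them with an estimated correlation. By limma's camera test the adjusted p were 1.20e-27 for interferon, 4.23e-20 for G1/S, 1.37e-19 for G2/M, 2.14e-08 for unfolded protein, 6.17e-10 for cholesterol and 6.42e-11 for histone genes. With an estimated correlation the camera values were adjusted p = 0.456, 0.444, 0.402, 0.456, 0.224 and 0.122 in that order. By fry the adjusted p were 0.116, 0.0581, 0.0511, 0.115, 0.0127 and 0.00136 in the same order. Fry also called the inflammatory and luminal prostate lists. By edgeR's quasi-likelihood test 1963 genes were higher and 2078 lower. These counts rest on a spread pooled over the tight vehicle pair and the looser shGFP and knockdown pairs. Leaving out the first shGFP library gave 2328 genes, and leaving out the first or second vehicle library 726 or 643. RSAD2, MX2, CXCL10 and CST1 did not pass without the first vehicle library (edgeR adjusted p = 0.303, 0.252, 0.178 and 0.128) or the second (0.325, 0.27, 0.193 and 0.137, adjusted). Without the first shGFP library RSAD2, MX2 and CXCL10 missed the threshold (edgeR adjusted p = 0.147, 0.1 and 0.0998), and RSAD2 and MX2 without the second (edgeR adjusted p = 0.0903 and 0.0522). Without a filter on low counts RSAD2, MX2, CXCL10 and CST1 missed it (edgeR adjusted p = 0.288, 0.222, 0.225 and 0.0961), and RSAD2 by limma-voom (adjusted p = 0.0506).

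Genes called in both knockdown and vehicle against shGFP numbered 532 higher in both and 586 lower in both, where independent lists would share 237.6 and 288.3, and simulated unchanged groups gave 0 in both directions, with a mean of at most 0.05 genes lower in a comparison, so this count does not size the effect of sharing controls. The fold changes had r = 0.23 and a covariance of 0.308, against r = 0.61 and a covariance of 0.132 in the simulated groups. Over genes of 5 CPM or more the covariance was 0.121, and 0.108 and 0.038 with another shGFP library for each comparison. Part of the excess may come from the shared controls. PAEP, CST4, CST1 and LDB3 are among the genes lower in both.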

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

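The tests of the shGFP level of cell-cycle and interferon genes, of interferon against cell-cycle genes, of the hairpin difference, of controls not shared and of markers other than COL1A1 were chosen only after the result was seen. The hairpins, with 1 library each and a spread taken from the shGFP and vehicle pairs, differed in 35 genes by edgeR's test of sh1 minus sh2, among them RSAD2 at -4.87. Lists also differed by limma's camera test: interferon genes had a median of -1.91, stress response genes -0.77, mitochondrially encoded genes 0.91, G2/M genes 0.46, G1/S genes 0.44, epithelial junction genes -0.23, miR-181 targets -0.21, immediate early genes -0.16, inflammatory genes -0.05 and epithelial-mesenchymal genes -0.03. None of these lists was called with an estimated correlation.

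Cell-cycle genes were lower in the knockdown libraries. The shGFP libraries were not high beside vehicle, since the G2/M median of the knockdown against vehicle was -3.48 and vehicle itself lay above shGFP. Delivery differs in that comparison, so whether shGFP was high for lentiviral cells cannot be told. A trend with GC content or transcript length is argued against as the whole cause, since the median was -2.12 after the trend was removed and -2.23 before. Interferon response as the cause cannot be told apart: sh2, with the higher interferon genes, had the lower G2/M genes, by a median of 0.46 between the bounds set, whereas vehicle lay above shGFP in both lists (2.79 and 0.98) and sh1 below vehicle in both (-1.51 and -3.19), comparisons in which delivery differs too. Loss of the circular RNA, the biological difference the design names, stays open and may also act through other routes.

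Interferon genes were higher in the knockdown libraries, and more so with sh2. A hairpin-specific difference cannot be told apart from a difference between libraries, with 1 library per hairpin: sh1 minus sh2 had a median of -1.91 over the list, or -1.82 with members at 0 counts put at their bound. Unusually low interferon genes in the shGFP libraries cannot be told apart, since sh1 lay below the vehicle libraries (median -1.51) and sh2 above them (median 0.46), and the vehicle cells had received plasmid. A response to the hairpin, the virus or the circular RNA may each contribute, although the shGFP cells also received a hairpin by lentivirus.

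Genes lower in both knockdown and vehicle than in shGFP numbered 586, and shared shGFP libraries with no effect cannot be told apart by the simulated count of at most 0 (1 with a pooled spread): the bound set beforehand on it was wrong, because unchanged groups have almost no calls to share (0.05 and 0 genes lower on average, against 2772 and 2078 observed). The noise of single shGFP libraries cannot be told apart from a shared effect either: the covariance was 0.308 against 0.132 in the simulated groups, but with another shGFP library for each comparison, the covariance over genes of 5 CPM or more was 0.108 and 0.038, against 0.121 with both shared, so 1 pairing lay between the bounds set. For blood cells or fibroblasts in the shGFP libraries, the bound set beforehand left the question open, because COL1A1 reached 70.91 CPM there; it was in all 7 libraries, and at 299 and 223 CPM in the knockdown. The markers other than COL1A1 argue against fibroblasts and PTPRC-bearing leukocytes, since the highest of COL1A2, COL3A1 and PTPRC in a shGFP library was 1.40 CPM, although blood markers had a median of -1.44 and fibroblast markers of -0.55 in vehicle against shGFP, and the leukocyte genes LILRB1 (10.3 and 23.5 CPM) and LAPTM5 (20.3 and 15.3 CPM) were counted in shGFP. A difference particular to the shGFP cells, such as their hairpin or passage, stays open and may be biological.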

How the results depend on the processing

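The fit of both arms apart for opposite-direction genes, the fit without mitochondrial genes, the fits of the hairpins without a library, the lists on an arm alone and the knockdown against vehicle were chosen only after the data were seen. Scaling by RLE or upper quartile, limma-voom and a non-robust prior kept every total count of genes called within 1.5 times its value. Of these settings the list counts were rerun with RLE only, and stayed at 10 and 9. The knockdown count of 5190 was 2063 against a fold of 1.5 and 3178 on its own arm, and 3167 to 5158 without a library. The overexpression count of 1 was 20 without a filter, 7 by DESeq2, 6 by likelihood ratio and 2224 on its own arm, and 1 to 1 without a library. The difference of effects (1488) was 3233 without a filter, 2773 by DESeq2, 3022 by likelihood ratio and 2671 with the hairpins separate, and 219 to 2503 without a library. Vehicle against shGFP (4041) was 643 to 5159 without a library. For sh1 (5121) the range without a library was 2962 to 11475, and for sh2 (3740) it was 2040 to 10567, with 5821 without a filter. For sh1 minus sh2 (35) the counts were 1093 without a filter, 7 at a mean of 5 CPM, 461 by DESeq2 and 777 by likelihood ratio, and 38 to 5830 without a library. Opposite-direction genes (0) were 9 without a filter, 3 by DESeq2, 2 by likelihood ratio, 449 on each arm alone and 0 to 0 without a library. Of the lists called by camera in the knockdown (10), 0 were called with an estimated correlation; fry called 6 lists, 1 of which (luminal prostate genes) camera did not call. In the overexpression (9) an estimated correlation gave 0 and fry 2. Without a library the knockdown lists were 9 to 14 and the overexpression lists 8 to 10. The 4-group fits pool the spread of the tight vehicle pair with that of the looser shGFP and knockdown pairs (25.9% and 26.9%). Leaving out a vehicle library takes the tight pair out of that spread. The knockdown, vehicle against shGFP and difference counts without a vehicle library thus also carry this change of spread. Other causes of these changes were not tested. In the hairpin fits the spread comes from the shGFP and vehicle pairs alone. Leaving out a shGFP library leaves the vehicle pair (biological coefficient of variation 5.4%), and leaving out a vehicle library the shGFP pair (25.9%). The hairpin ranges without a library thus also carry this change of spread. Replicate numbers were not shown to pair the libraries (r of replicate 1 minus 2 was 0.082, 0.322 and 0.164 between groups), and the replicate block gave 5462 knockdown genes and 4291 for vehicle against shGFP. No named gene turned direction. In the knockdown 48 named results no longer passed, 7 newly passed and 1057 kept their side; in the overexpression 61 newly passed. A count of 0 allows up to 0.074 to 0.114 CPM per library, so genes near that level have fitted folds that depend on the prior count.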

Other observations

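The miR-181 test was fixed before its result was seen; the comparison of knockdown with vehicle was added after seeing the data. Against the vehicle libraries, the knockdown libraries had 51 of 54 G2/M genes lower (median -3.48) and 44 of 45 G1/S genes lower (median -2.72). Inflammatory genes had 18 of 30 lower and 1 higher (median -1.31), whereas cholesterol genes had 7 higher and 7 lower (median -0.12) and interferon genes 3 higher and 3 lower (median -0.16). These counts are by edgeR's quasi-likelihood test, which called 7244 genes in this comparison, and they set lentiviral against transfected cells. Of the calls of the knockdown against shGFP, 1397 were higher and 1764 lower against both controls, where independent lists would share 434 and 507.6. Another 45 were higher against shGFP and lower against vehicle, and 89 the reverse. Both comparisons use the same knockdown libraries, so part of this overlap is built in.

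The hypothesis that circCSNK1G3 holds miR-181 away from its targets predicts that genes with a miR-181 seed match in the 3' UTR are lower in the knockdown. The longest annotated 3' UTR of each gene was used, and filters on its length and on mean CPM left 12964 genes. Of these, 3034 held the 7-base match. Their median log2 fold change in the knockdown differed from that of the other genes by -0.09, and 209 control 7-mers of the same bases gave -0.137 to -0.07 between their 5% and 95% quantiles. In the overexpression the difference was 0.008, with controls from 0.002 to 0.023. The test argues against a miR-181 effect on mRNA levels that is larger than that of matched 7-mers, and says nothing of effects on translation or on a few targets. Of the fixed miR-181 target list 7 genes fell in the knockdown and 5 rose, CBX7 among the latter.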
